A study of Emiliania huxleyi CCMP1516 with 36 samples.

How the data were processed

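RNA was measured in 36 libraries of Emiliania huxleyi, 4 biological replicate cultures in each of 9 groups: the parent cultures, and cultures with the vehicle or HHQ at 1, 10 or 100 ng/ml after 24 and 72 h. Libraries were made with a stranded poly(A) kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.38 and Salmon 0.12.0. The reference transcripts and the settings of both tools are not given in the sources used here. The deposited values are estimated counts per gene, not normalized, and 45.8% of them were not whole, so they were rounded to whole numbers before testing.

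The table held 37212 genes, of which 33295 had at least 1 count, and each of its 36 value columns matched 1 sample by name. Totals ran from 5679128 to 42602884 counts. Replicates of a group differed by 5.87 to 225 chi-square units per gene over 54 pairs, so no library was treated as a repeat of another. A gene table of the organism's RefSeq assembly gave names for 37202 of the 37212 identifiers, and 778 genes carry a symbol, 661 of them tested. The strain named by the labels' organism field is the reference strain, whereas the cultures were CCMP2090, and the effect of any sequence difference on the counts was not examined. What a symbol stands for is taken from its usual meaning.

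Genes were filtered with edgeR's filterByExpr, which kept 26494, and scaled with TMM (trimmed mean of M values) factors. Differences were tested with edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3, 1 fit over all 36 libraries with a mean per group, two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. The median biological coefficient of variation was 0.287. Interactions compared the HHQ response at 72 h with that at 24 h. CPM values are TMM-normalized, and log CPM used a prior count of 2.

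Gene groups were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 23 lists in each comparison, and again with a correlation estimated per list. The lists first planned on product names could not be applied, because the names used here are symbols. Lists of symbols were therefore written after the identifiers were seen and before any test, and a list needed 5 tested members; of 24 lists the flagellar one had 0 tested genes of 5 and was left out. With an estimated correlation the Lhcf list held for 100 ng/ml HHQ at both times, and the replicative polymerase list for 10 ng/ml at 24 h and 100 ng/ml at 72 h; the other calls against vehicle did not hold except DNA recombination for 10 ng/ml at 24 h. Near-identical copies, such as Arf4-1 and Arf4-2, POLD1-1 and POLD1-2, PSBO-1 and PSBO_2, and members of the Lhcf family, can share reads that Salmon divides between them, so the value of each single copy is uncertain.

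The rule for naming genes, the groups, the tests and most alternatives were set before the data were examined. For 100 ng/ml HHQ against vehicle it takes the 10 rising and 10 falling genes with a symbol and the largest log2 fold change, and for other comparisons 5 and 5. Each needed an adjusted p under 0.05, a mean of at least 1 CPM over the 8 libraries, and no overlap between the 4 and 4 libraries (a condition not used for interactions). It adds up to 4 members with the smallest p of each list with a called member in the 100 ng/ml comparisons, and up to 2 identifiers without a symbol in each direction. Dihydroorotate dehydrogenase and poly(ADP-ribose) polymerase genes, also planned, carry no symbol and were not analysed here. Some genes that the rule takes are not reported here. Other levels given for these genes, such as CPM in further groups, are descriptive.

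Shares of counts were compared with exact two-sided permutation tests of 4 against 4 libraries, adjusted over 8 comparisons per measure. For the Lhcf share, where replicate numbers pair the libraries, an exact sign-flip test over the 4 pairs was added after seeing the data. For genes with 0 counts in a group, folds are lower bounds against a floor of 3 counts over the group. For 1 to 3 counts a 95% interval of the ratio is given. Floors and intervals cover counting error only. Shared vehicle libraries were allowed for with 5 simulated draws of unchanged groups, the vehicle included, and by dividing the controls.

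Replicate numbers in the labels are shared across groups, and the labels do not say that a number marks a shared batch. Correlations of deviations from the group means between same-numbered libraries were over 0.1 for every pair in HHQ 10 against vehicle at 24 h (0.174 to 0.5), HHQ 1 (0.284 to 0.445) and HHQ 10 (0.201 to 0.438) against vehicle at 72 h, HHQ 100 against HHQ 10 at 24 h (0.12 to 0.422) and 72 h (0.134 to 0.45), and HHQ 10 against HHQ 1 at 72 h (0.214 to 0.422). The numbers were read as pairing the libraries in these comparisons only. At both times this pairs HHQ 100 with HHQ 10 and HHQ 10 with vehicle, but not HHQ 100 with vehicle. A batch shared by number would pair these too, so the cutoff of 0.1 leaves the comparisons not read as paired undecided. This reading came from the same data and is uncertain at 72 h. There a library correlated best with its own number in 3 of 4 cases for HHQ 10 against vehicle and against HHQ 1. It did so in 2 of 4 cases for HHQ 100 against HHQ 10 at 72 h, and in 4 of 4 in the other comparisons read as paired.

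The edgeR test was also tested on simulated data drawn from the real means and library sizes of 4 comparisons of HHQ with vehicle, with 50 genes changed at each of 4 fold sizes among 26494. For 1.5-fold, 2-fold, 4-fold and 8-fold changes, 0%, 20%, 64% and 82% were recovered for HHQ 100 at 24 h, 4%, 22%, 76% and 80% at 72 h, and 8%, 10%, 72% and 72% for HHQ 10 at 72 h. False calls were 5 of 88, 6 of 97 and 4 of 85. Camera, simulated for HHQ 100 at 24 h alone, called the 1 shifted list of 30 genes and 0 of 20 unshifted lists. The simulated genes varied independently, so this says nothing about false calls of lists whose members vary together. The other comparisons, the interactions and the permutation tests were not simulated.

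The alternatives set beforehand were DESeq2's size factors in edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, the replicate number as a block, an absolute log2 fold change of at least 1, fry in place of camera, and leaving out each library in turn. Chosen after seeing the data were scaling by library totals alone, the replicate block within each time, the axis along which libraries of a group differed as a covariate, and fits of the 24 h replicates 1 to 3 or the 72 h replicates 1 and 2 or 3 and 4. The axis was computed from the deviations of the same tested genes. As a covariate it lowers residual variance by construction, so a higher count with it is not separate evidence.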

Results

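Emiliania huxleyi is a unicellular marine alga of the coccolithophores, and 2-heptyl-4-quinolone (HHQ) is an alkylquinolone that some bacteria release as a signalling molecule. Axenic cultures of strain CCMP2090 received HHQ at 1, 10 or 100 ng/ml or the vehicle alone, and polyadenylated RNA was sequenced after 24 and 72 h. The 36 libraries fall into 9 groups of 4 biological replicate cultures: the parent cultures at time 0, and the vehicle and 3 HHQ doses at each of the later times. Library totals ran from 5679128 estimated counts in HHQ 1 replicate 3 at 72 h to 42602884 in HHQ 10 replicate 3 at 24 h. In these same libraries 16386 and 26369 genes reached 10 counts. Means are over 4 libraries. The value after ± is the SD of a mean or, for a log2 fold change, its standard error (SE).

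Libraries of a group did not scatter evenly. At 24 h replicate 4 stood apart from replicates 1 to 3 in the vehicle, HHQ 10 and HHQ 100 groups, as replicate 1 did among the parent cultures and in HHQ 1. At 72 h replicates 1 and 2 differed from replicates 3 and 4 in all 4 treatments. Results are therefore also given within these sets where the call or the size moved.

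**Figure D1:**
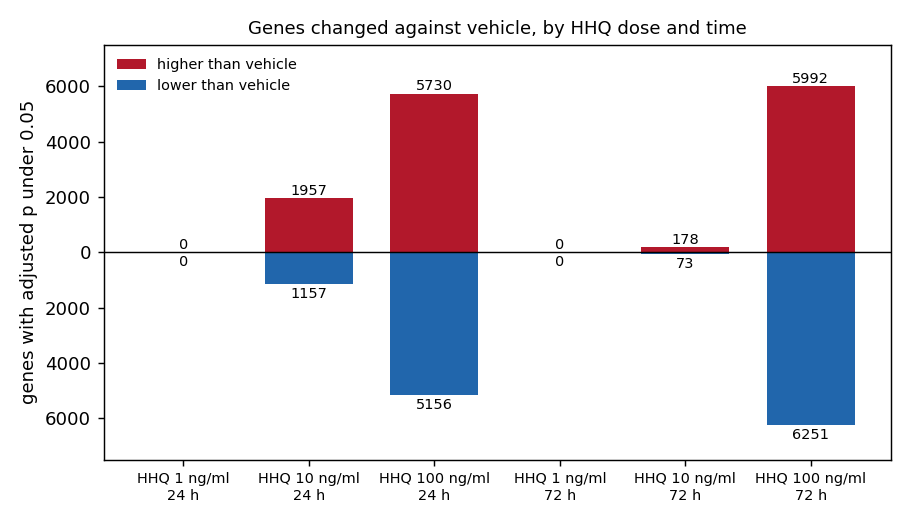
Number of genes higher (above 0) and lower (below 0) than in the vehicle group of the same time, by HHQ dose and time, among 26494 tested genes with adjusted p under 0.05 (4 libraries per group). No gene passed at 1 ng/ml, and the counts at 10 ng/ml were 1957 and 1157 at 24 h against 178 and 73 at 72 h; with library totals alone as scaling, most called genes at 10 and 100 ng/ml were higher than vehicle.

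The comparison of 100 ng/ml HHQ with vehicle at 24 h asked how the alga responded to the highest dose early on. Genes of the light-harvesting antenna, the Lhcf family that binds fucoxanthin and chlorophyll, fell together: 63 of 78 tested members were lower and 2 higher, with a median log2 fold change of −2.06. Lhcf32 dropped from 34160 ± 10300 to 2888 ± 618 TMM-normalized CPM, 11.8-fold lower, and Lhcf74 and Lhcf65 were 24.2-fold and 12.5-fold lower. The polyketide synthase gene PKS5 went the other way, from 3.08 ± 1.22 to 67.2 ± 6.24 CPM, 22.1-fold higher (log2 fold change 4.46 ± 0.34). The small GTPase genes Arf4-1 and Arf4-2, similarly named copies whose reads cannot be fully separated, rose 10.0-fold and 10.7-fold, and VPS34-1, named for a phosphatidylinositol 3-kinase of endosomal traffic, rose 7.67-fold.

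In all, 10886 of 26494 genes (41.1%) changed at this dose and time, 5730 higher and 5156 lower (edgeR quasi-likelihood test, adjusted p under 0.05). The adjusted p was 5.03e-11 for PKS5, 1.04e-10 for Lhcf32 and 2.27e-07 for Lhcf74. The balance between higher and lower genes depended on scaling. With library totals alone, the median log2 fold change of all tested genes was 0.873 at 24 h and 1.17 at 72 h for 100 ng/ml, and 0.262 and 0.129 for 10 ng/ml, so that 11545 genes were higher and 1803 lower here (86.5% higher in place of 52.6%). Gene groups are described relative to the trimmed-mean scaling.

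Lhcf genes together took 13.5% ± 0.619 of all counts in the vehicle cultures at 24 h and 3.94% ± 0.486 with 100 ng/ml HHQ (exact two-sided permutation test p = 0.0286, the smallest that 4 against 4 libraries allow; 0.0458 adjusted over 8 comparisons). The share was 13.7% against 4.09% in replicates 1 to 3 and 12.8% against 3.46% in replicate 4. The Lhcf list was called by camera (adjusted p = 2.05e-43 over 23 lists, and adjusted p = 0.0127 with an estimated correlation). It also kept a median of −1.21 with library totals, 53 members lower and 6 higher. Adjusted over the list alone, 63 members fell and 3 rose.

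**Figure D2:**
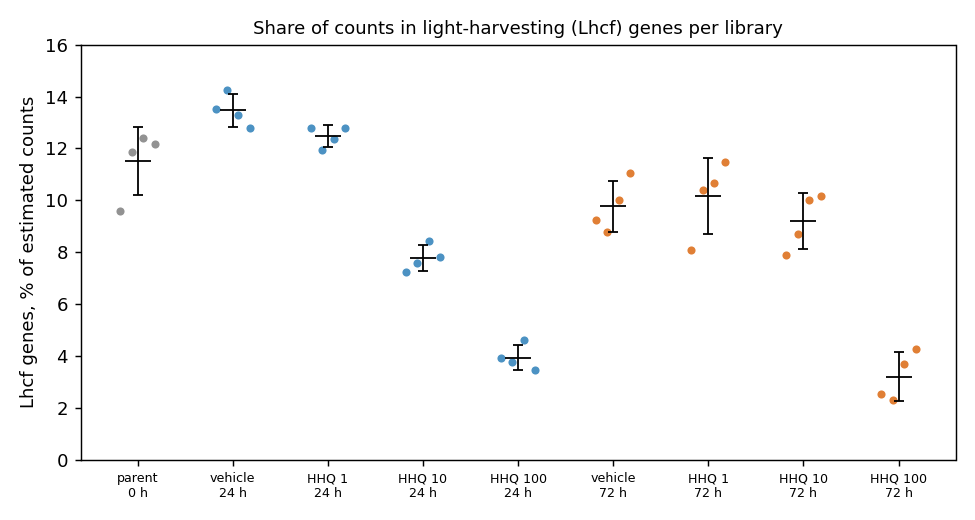
Percent of all estimated counts in Lhcf genes, 1 point per library; bars are the mean and SD of 4 libraries. The vehicle mean was 13.5% at 24 h and 9.77% at 72 h, and with 100 ng/ml HHQ it was 3.94% and 3.20%.

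Of 12 photosystem and pigment genes 8 fell and 0 rose, also adjusted over the list alone, with a median of −0.69 (0.136 with library totals). PSBO-1 and PSBO_2, which name copies of the oxygen-evolving complex subunit, were both 5.39-fold lower, and PSAE of photosystem I was 2.99-fold lower (log2 fold change −1.58 ± 0.19). The list was called with the preset correlation (adjusted p = 9.09e-05) but not with an estimated one (adjusted p = 0.557). It was the only other list called of the 23. Of 19 glycolysis genes 8 fell and 3 rose (10 and 4 adjusted over the list alone; median −0.641, 0.205 with library totals; adjusted p = 0.0835), with the phosphoglycerate kinase genes PGK_1 and PGK_2 3.90-fold and 3.33-fold lower and PGK1 2.17-fold higher. In the pentose phosphate pathway 2 of 6 fell, 6PGL 2.54-fold, and 1 rose (median −1.02, adjusted p = 0.203). Of 11 isoprenoid genes 6 fell and 1 rose (median −0.71, 0.227 with library totals; adjusted p = 0.203), among them HMGR2 and HMGR3, 2.93-fold and 2.77-fold lower.

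Of 40 vesicle coat genes 20 rose and 5 fell (20 and 6 adjusted over the list alone; median 0.381, 1.18 with library totals; adjusted p = 0.165, and 0.000959 with library totals), with AP2A-1 1.89-fold and SEC24B 2.13-fold higher. Of 39 SNARE, SM protein and tether genes 16 rose and 5 fell (16 and 7; adjusted p = 0.203), including Vps45 at 2.18-fold and STXPM-2 at 3.45-fold. Of 27 ESCRT, retromer and vacuolar sorting genes 10 rose and 4 fell (10 and 5; adjusted p = 0.293). The 31 Rab, Arf and Arl genes split 9 higher to 7 lower (10 and 7), with a median of −0.362 (0.529 with library totals) although the test leaned up (adjusted p = 0.797); Rab5a was 2.87-fold higher. None of these lists was called with the trimmed-mean scaling. Of 20 V-type ATPase genes 5 fell and 0 rose (2 and 0; median −0.256, 0.572 with library totals; adjusted p = 0.169).

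Among nitrogen genes, 6 of 13 ammonium transporters fell and 0 rose, likewise adjusted over the list alone (median −0.789, 0.107 with library totals; adjusted p = 0.113, and 0.0107 with library totals), and AMT16 was 5.28-fold lower. The 16 nitrate, urea and glutamine genes divided 5 to 5 in both counts (adjusted p = 0.874): the nitrate transporter NRT1 was 3.05-fold higher, and the glutamine synthetase genes GLN3 and GLN4 were 4.01-fold higher and 3.69-fold lower. In the urea cycle 3 of 6 rose, with ASL1 2.24-fold and CPS1 2.15-fold higher, and 1 fell (adjusted p = 0.293). Of 10 polyketide synthases 3 rose and 3 fell (median −0.00659, 0.876 with library totals; adjusted p = 0.886), PKS3 falling 5.09-fold. Of 9 fatty acid genes 3 rose and 2 fell (adjusted p = 0.874), and FADS1 and FADS2, named for desaturases, were 1.70-fold and 1.81-fold higher.

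The remaining lists held few or divided calls. Of 12 replicative DNA polymerase and clamp loader genes 4 rose and 0 fell (adjusted p = 0.293), with RFC1 4.13-fold higher, and of 14 DNA recombination and repair genes 4 rose and 1 fell (adjusted p = 0.874). Calcium and ion transport genes numbered 5 higher and 8 lower of 19 (6 and 8; median −0.0252, 0.761 with library totals; adjusted p = 0.993), with the Na+/H+ antiporter gene NHA1 5.10-fold higher and the channel gene TPC1 4.49-fold lower. Of 8 genes for inorganic carbon transport, carbonic anhydrase and the coccolith protein GPA 3 fell and 0 rose (4 and 0; median −0.815, 0.046 with library totals; adjusted p = 0.203), and the carbonic anhydrase gene CA1 was 7.41-fold lower. Glutathione and antioxidant genes split 3 higher to 2 lower of 21 (2 and 1; median −0.0545, 0.752 with library totals; adjusted p = 0.955), actin and Arp2/3 genes 1 to 1 of 17 (median −0.299, 0.449 with library totals; adjusted p = 0.665), ECH genes 2 to 1 of 10 (adjusted p = 0.392) and aldehyde dehydrogenases 4 to 2 of 9 (adjusted p = 0.665). Where a single pair of counts is given, here and for this dose at 72 h, the counts adjusted over the list alone were equal. With library totals alone the calls of CPO, ASS1, RPE2, GSH5, Sar1b, GPA, ACT-5, PKS9 and ALDH3 were lost. Of genes without a symbol, EMIHUDRAFT_260382 was at least 102-fold higher against a vehicle group with 0 counts, and EMIHUDRAFT_436633 fell by 8.22 ± 0.98 on the log2 scale.

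At 72 h with the highest dose antenna genes were again lower than in vehicle, and genes of DNA replication were higher, as were PYC1 and IDH1. Of 78 Lhcf genes 70 fell and 1 rose (71 and 1 adjusted over the list alone), with a median log2 fold change of −2.11, and Lhcf32 was 11.8-fold lower than vehicle. Of 12 replicative polymerase and clamp loader genes 10 rose and 0 fell (11 and 0), with a median of 3.33. The clamp loader genes RFC3 and RFC2 were 24.8-fold and 15.1-fold higher, and POLD1-1 and POLA1, which name catalytic subunits of DNA polymerases delta and alpha, 7.02-fold and 7.45-fold. PYC1, named for pyruvate carboxylase, went from 1.06 ± 0.12 to 48.4 ± 11.8 CPM, 45.2-fold higher (log2 fold change 5.50 ± 0.33), and IDH1, named for isocitrate dehydrogenase, was 18.5-fold higher.

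This comparison gave 12243 changed genes (46.2%), 5992 higher and 6251 lower; with library totals alone 14505 were higher and 1593 lower (90.1% higher in place of 48.9%). The adjusted p was 1.08e-13 for PYC1, 4.98e-11 for Lhcf32 and 5.23e-07 for RFC3. The Lhcf share of counts was 9.77% ± 0.99 in vehicle and 3.20% ± 0.946 with HHQ (exact two-sided permutation p = 0.0286; 0.0458 adjusted). It was 9.01% against 2.41% in replicates 1 and 2, and 10.5% against 3.98% in replicates 3 and 4. Camera called 4 lists: Lhcf (adjusted p = 2e-40, and adjusted p = 0.0178 with an estimated correlation), the replicative polymerases (adjusted p = 1.51e-11, and adjusted p = 0.0199 with an estimated correlation), photosystem and pigment genes (adjusted p = 0.000104, and adjusted p = 0.331 with an estimated correlation) and isoprenoid synthesis (adjusted p = 0.0147, and adjusted p = 0.331 with an estimated correlation). With library totals the Lhcf median was −0.927, with 50 members lower and 4 higher.

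Photosystem and pigment genes fell in 9 of 12 cases with a median of −0.932 (0.28 with library totals), PSBO_2 by 4.11-fold. Isoprenoid genes fell in 8 of 11 cases (median −1.04, 0.00713 with library totals), HMGR2 and HMGS1 by 3.97-fold and 2.88-fold. Of 14 DNA recombination and repair genes 7 rose and 1 fell (median 1.22, adjusted p = 0.0602); the mismatch repair gene mutS and the topoisomerase VI gene Top6A were 33.2-fold and 20.8-fold higher. TYMK, named for thymidylate kinase, was 14.2-fold higher. PKS5 was 14.4-fold higher, and of 10 polyketide synthases 5 rose and 2 fell (adjusted p = 0.388), PKS3 again lower at 6.46-fold. Of 9 fatty acid genes 3 rose and 3 fell (adjusted p = 0.511): FADS1 and FADS2 were 5.15-fold and 5.31-fold higher (log2 fold change 2.36 ± 0.20 for FADS1) and KAS1 3.64-fold lower.

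Of 16 nitrate, urea and glutamine genes 8 rose and 4 fell (adjusted p = 0.202), with GLN3 10.9-fold and the nitrite reductase gene NII1 9.23-fold higher and the urea transporter gene DUR3 10.3-fold lower. Ammonium transporters fell in 6 of 13 cases and rose in 1 (median −0.738, 0.327 with library totals; adjusted p = 0.202, and 0.0321 with library totals), with AMT13 3.10-fold lower, and 4 of 6 urea cycle genes rose and 1 fell (adjusted p = 0.388). Glycolysis genes divided 6 to 6 of 19 (6 and 8; median −0.0628, 1.14 with library totals; adjusted p = 0.569), the phosphofructokinase gene 16PFK1 being 6.95-fold higher and PGK_1 4.93-fold lower, and pentose phosphate genes 2 to 2 of 6 (2 and 3; median −0.505, 0.677 with library totals; adjusted p = 0.539). Coats rose in 16 and fell in 6 of 40 cases (19 and 6; adjusted p = 0.107, and 0.000197 with library totals), GTPases 12 and 10 of 31 (12 and 11; adjusted p = 0.428; median −0.147, 0.842 with library totals, against a test that leaned up), with Arf4-1 and Arf4-2 11.5-fold and 12.1-fold higher. SNAREs and tethers divided 8 to 8 of 39 (7 and 6; adjusted p = 0.656), and ESCRT and retromer genes 8 to 6 of 27 (adjusted p = 0.656), VPS60 being 5.65-fold lower.

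V-type ATPase genes fell in 5 and rose in 1 of 20 cases (4 and 1; median −0.367, 0.807 with library totals; adjusted p = 0.237). Of the 8 inorganic carbon genes 3 fell and 0 rose (median −0.76, 0.299 with library totals; adjusted p = 0.239), CA1 by 5.69-fold. Calcium and ion transport genes divided 6 to 6 of 19 (median −0.0623, 1.14 with library totals, against a test that leaned up; adjusted p = 0.656), with CCX1 3.29-fold higher. Glutathione and antioxidant genes divided 6 higher to 5 lower of 21 (median 0.132 against a test that leaned down; adjusted p = 0.882), and actin and Arp2/3 genes 1 to 4 of 17 (1 and 3; median −0.143, 1.07 with library totals; adjusted p = 0.656). ECH genes divided 4 to 1 of 10 (adjusted p = 0.213) and aldehyde dehydrogenases 4 to 2 of 9 (adjusted p = 0.539). With library totals alone PSAE, AMT13, GLN4, ASS1, gpmA, 6PGL, RPE2, GGT1, VAMP7-1, IST1, GPA, ARP2, ARPC2, SLC4-1 and HMGS2 lost their calls. EMIHUDRAFT_436112 was at least 105-fold higher against 0 vehicle counts and EMIHUDRAFT_97151 at least 438-fold lower.

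The intermediate dose, 10 ng/ml, gave its larger response at 24 h, and among genes with a symbol it was led by DNA replication genes. Of genes without a symbol, EMIHUDRAFT_447150 and EMIHUDRAFT_105354 were at least 88.5-fold and 68.5-fold higher against 0 vehicle counts. EMIHUDRAFT_438326, with 0 counts at 10 ng/ml, was at least 75.7-fold lower. Of 12 replicative polymerase and clamp loader genes 11 rose and 0 fell, with a median log2 fold change of 3.73. POLE1, the catalytic subunit of DNA polymerase epsilon, was 27.7-fold higher (4.79 ± 0.40) and RFC3 23.9-fold higher; POLD1-1 stood at 19.3 ± 3.97 CPM against 1.10 ± 0.13 in vehicle. TUBB1, a beta-tubulin, and Top6A were 22.8-fold and 20.6-fold higher. Lhcf genes fell in 45 of 78 cases and rose in 0 (50 and 1 adjusted over the list alone), with a median of −0.833, Lhcf39_2 by 3.27-fold and Lhcf38 by 4.76-fold.

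A total of 3114 genes changed (11.8%), 1957 higher and 1157 lower, and with library totals alone 1825 were higher and 286 lower (86.5% higher in place of 62.8%). Same-numbered libraries varied together here, and with the replicate number as a block within each time 5479 genes changed, and 6191 with the axis along which libraries of a group differed as a covariate. The adjusted p was 1.45e-10 for POLE1 and 3.06e-07 for Lhcf39_2. The replicative polymerase list was called with either correlation (adjusted p = 2.58e-33, and adjusted p = 3.16e-05 with an estimated correlation). DNA recombination and repair genes, 5 of 14 higher and 0 lower (5 and 1 adjusted over the list alone), were also called with either (median 0.714, adjusted p = 0.00459, and adjusted p = 0.0128 with an estimated correlation). With the block they missed the threshold at a similar median (0.766, adjusted p = 0.0513). The Lhcf list (adjusted p = 9.3e-19), the photosystem and pigment list with 2 of 12 lower (0.0195) and the coat list with 11 higher and 2 lower of 40 (0.0366) lost their calls with an estimated correlation (adjusted p = 0.124, 0.698 and 0.698). The photosystem call was also lost with library totals (adjusted p = 0.0582) and the coat call with DESeq2 size factors (adjusted p = 0.0581). With library totals upward calls were added for actin and Arp2/3 (median 0.826, adjusted p = 0.0015, 7 of 17 higher in place of 3), urea cycle (median 0.731, adjusted p = 0.0206) and V-type ATPase genes (median 0.413, adjusted p = 0.0479). The Lhcf share of counts fell to 7.77% ± 0.506 (exact two-sided permutation p = 0.0286; 0.0458 adjusted), 7.76% in replicates 1 to 3 and 7.8% in replicate 4, and was lower in all 4 same-numbered pairs (exact two-sided paired p = 0.125, the smallest that 4 pairs allow). With library totals the Lhcf median was −0.549 with 28 members lower, and that of the replication genes 3.99; Lhcf74, 3.49-fold lower (log2 fold change −1.80), lost its call there at −1.56, as it did without HHQ 10 replicate 1 (−1.63) or 2 (−1.65).

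At 72 h the response to 10 ng/ml was narrower. Arf4-2 and Arf4-1 were 3.73-fold and 3.04-fold higher (log2 fold changes 1.90 ± 0.25 and 1.61 ± 0.24), NII1 was 3.49-fold, PYC1 2.83-fold and POLD1-1 2.62-fold higher, and no gene with a symbol was called lower without the replicate block. Same-numbered libraries varied together here too, and with the block within time 2 Lhcf genes, 1 ammonium transporter and 1 glycolysis gene were called lower. The Lhcf share of counts was 9.19% ± 1.08, against 9.77% ± 0.99 in vehicle (exact two-sided permutation p = 0.486, libraries not paired). It was lower in all 4 same-numbered pairs, with differences of −1.34 to −0.000554 percentage points (exact two-sided paired p = 0.125, the smallest that 4 pairs allow). It was 8.3% against 9.01% in replicates 1 and 2 and 10.1% against 10.5% in replicates 3 and 4. In total 251 genes changed (0.947%), 178 higher and 73 lower, and 135 changed with library totals alone (91.1% higher in place of 70.9%).

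The 5 named genes had adjusted p from 5.22e-05 for Arf4-2 to 0.0143 for NII1, and NII1 (log2 fold change 1.80) lost its call with library totals (1.93) or without vehicle replicate 4 or HHQ 10 replicate 1 (1.64 in both). The replicative polymerase list was called (2 of 12 higher, 5 adjusted over the list alone, median 1.14; adjusted p = 3.75e-08, and adjusted p = 0.0948 with an estimated correlation). So were, upward, the polyketide synthases (adjusted p = 0.0017), fatty acid genes (0.0119), V-type ATPase (0.000881) and urea cycle (0.048). The Lhcf list was called downward (median −0.117, adjusted p = 0.0338), but with library totals its median was 0.0313 and the call was lost (adjusted p = 0.0827), while Rab, Arf and Arl genes were called (adjusted p = 0.0264). With an estimated correlation none of the lists called here was (adjusted p = 0.495, 0.0948, 0.602, 0.456 and 0.83 in the order given after the polymerases). The count depended on which libraries were used: 75 genes changed with replicates 1 and 2, 17 with replicates 3 and 4, 725 with the replicate number as a block within each time, 875 with the axis as a covariate, 578 by DESeq2, 57 with the compared groups alone, 165 without vehicle replicate 1 and 161 without HHQ 10 replicate 4. POLD1-1 lost its call when only the 2 compared groups were fitted, at a log2 fold change of 1.38 in place of 1.39. With replicates 3 and 4, where 2 libraries stand against 2, none of the 5 genes was called, at 1.62 for Arf4-2, 1.67 for Arf4-1, 1.78 for NII1, 1.41 for PYC1 and 0.85 for POLD1-1. With replicates 1 and 2 Arf4-1 (1.59), NII1 (1.85) and PYC1 (1.61) were not called.

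The lowest dose, 1 ng/ml, left Lhcf and replication genes near their vehicle levels. Lhcf genes took 12.5% ± 0.415 of counts at 24 h against 13.5% ± 0.619 in vehicle (exact two-sided permutation p = 0.0857; 0.114 adjusted), and 10.2% ± 1.46 at 72 h against 9.77% ± 0.99 (p = 0.686 by the same exact test). At 72 h, where these libraries were read as paired, the share was lower in 1 of 4 same-numbered pairs (exact two-sided paired p = 0.625). POLD1-1 stood at 1.2 ± 0.269 and 0.835 ± 0.338 CPM at 24 and 72 h, beside 1.10 ± 0.13 and 1.09 ± 0.21 in vehicle, and PKS5 at 3.43 ± 1.24 and 3.81 ± 0.927 CPM beside 3.08 ± 1.22 and 2.94 ± 0.686. No gene passed in the edgeR test without a block or covariate at either time. At an unadjusted p under 0.05 there were 2045 genes at 24 h and 494 at 72 h, where chance gives 1325, and the DESeq2 Wald test called 12 and 8. At 24 h 3466 genes passed, 2508 higher and 958 lower, with the axis along which libraries of a group differed as a covariate, a setting chosen after the data were seen. That axis was computed from these same genes, so as a covariate it lowers residual variance by construction. Its scores are centred within each group, so it cannot take out a difference between groups. The replicate block within time, also chosen afterwards, gave 979 higher and 258 lower genes at 24 h. The numbers were not read as pairing these libraries, with correlations between same-numbered libraries of −0.168 to 0.362. A library correlated best with its own number in 3 of 4 cases, so pairing is not settled here.

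At 24 h camera called 7 lists upward at 1 ng/ml, including Lhcf (median 0.254; adjusted p = 4.11e-05; −0.146 and 0.29 with library totals), ammonium transporters (adjusted p = 0.00651) and actin and Arp2/3 genes (adjusted p = 0.00227), and none of the 7 held with an estimated correlation (adjusted p = 0.485, 0.408 and 0.471 for these). No member of any of them passed on its own without the replicate block. With the block within time, in libraries not read as paired, some members were called higher at 24 h. These were 3 ammonium transporters, 3 actin and Arp2/3, 2 isoprenoid, 2 inorganic carbon and 1 polyketide synthase genes, but no Lhcf or V-type ATPase gene. No list was called at 72 h, where library totals gave V-type ATPase an adjusted p of 0.0307. The median of all genes under library totals was −0.468 at 24 h. In simulated data with this comparison's depth and spread, 0%, 24%, 60% and 82% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered.

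**Figure D3:**
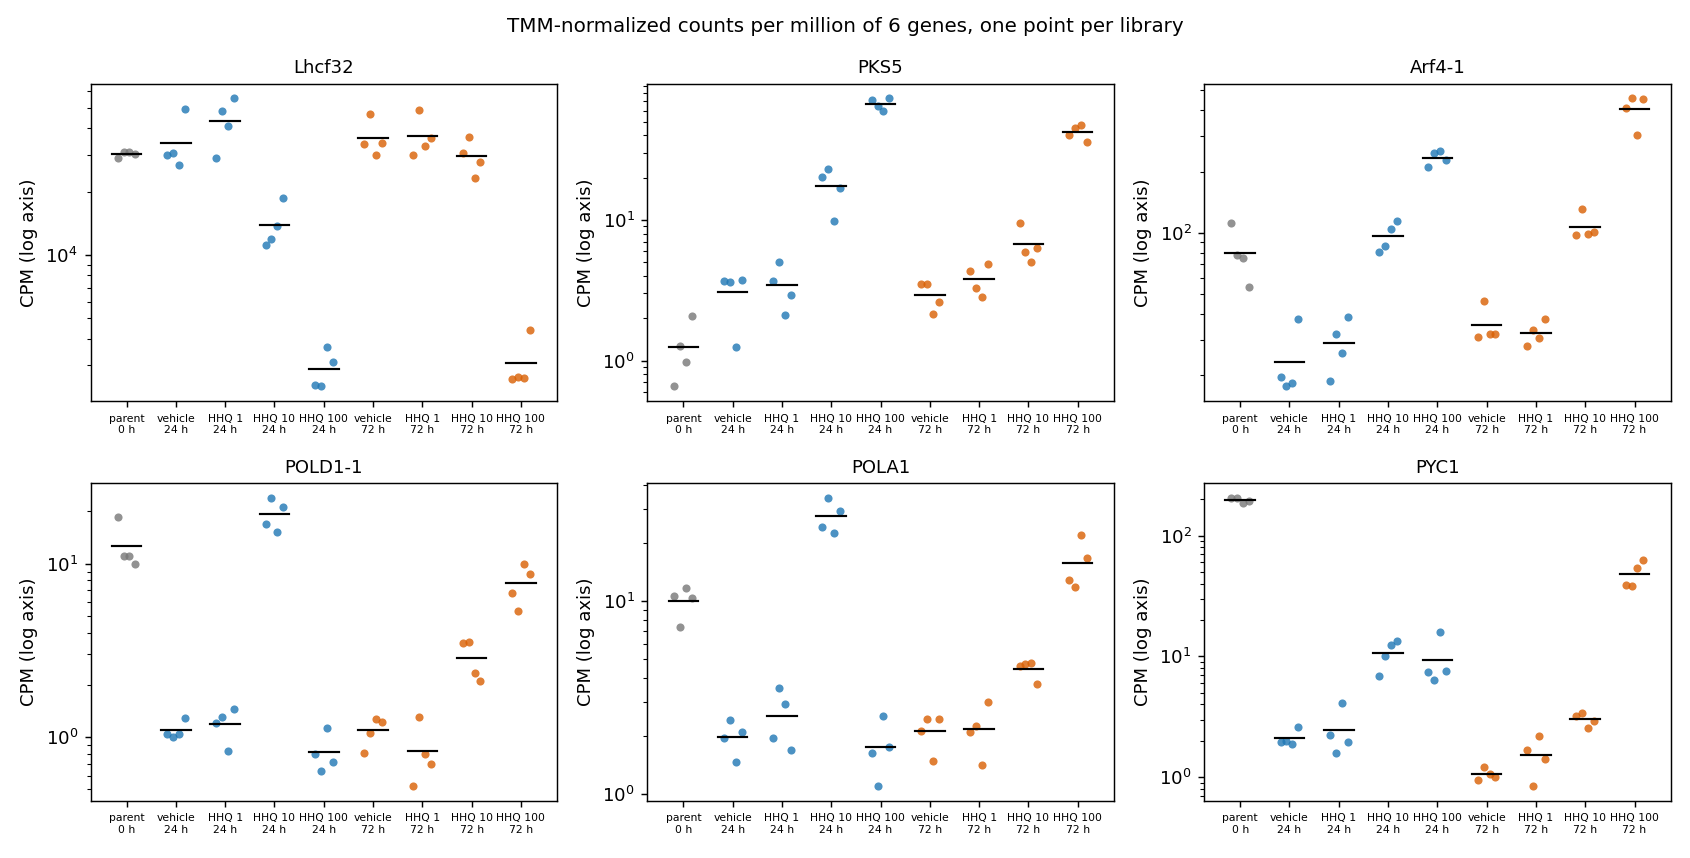
TMM-normalized CPM (log axis) of Lhcf32, PKS5, Arf4-1, POLD1-1, POLA1 and PYC1 in the 9 groups; points are libraries and bars the mean of 4. PKS5 was at 17.4 and 67.2 CPM at 24 h with 10 and 100 ng/ml HHQ, whereas POLD1-1 was at 19.3 and 0.820 CPM.

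Neighbouring doses were compared directly to ask where along the dose range expression changed. At 24 h POLD1-1 was 16.4-fold higher at 10 than at 1 ng/ml (log2 difference 4.04 ± 0.28) and then 23.4-fold lower at 100 than at 10 ng/ml (−4.55 ± 0.27). POLA1 was likewise 15.7-fold lower at 100 than at 10 ng/ml. PKS5 and VPS34-1 instead rose further, 3.87-fold and 4.19-fold. Lhcf genes fell at both steps, 48 of 78 lower and 3 higher from 1 to 10 ng/ml (median −1.1, adjusted p = 0.0885 with an estimated correlation) and 51 lower and 3 higher from 10 to 100 ng/ml (median −1.15, adjusted p = 0.0488 with an estimated correlation), and the medians were −0.415 and −0.589 with library totals. Adjusted over the list alone, 54 and 53 Lhcf genes fell at these steps and 3 rose at each.

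From 1 to 10 ng/ml at 24 h 6735 genes changed, 3826 higher and 2909 lower (7864 and 791 with library totals, 90.9% higher in place of 56.8%; median of all genes 0.738). From 10 to 100 ng/ml 4947 changed, 2516 higher and 2431 lower (5282 and 1157 with library totals, 82% higher in place of 50.9%; median of all genes 0.592), and 9273 with the replicate block within time. With the axis as a covariate the counts of these steps were 10939 and 9740. Replicative polymerases rose in 10 of 12 cases at the first step (11 adjusted over the list alone; median 3.02, adjusted p = 0.0011 with an estimated correlation) and fell in 8 of 12 at the second (10 adjusted over the list alone; median −2.68, and adjusted p = 0.000627 with an estimated correlation). DNA recombination genes fell in 5 of 14 cases and rose in 1 at the second step (6 and 1; median −0.623, and adjusted p = 0.0488 with an estimated correlation). With the block their call was lost at a similar median (−0.62, adjusted p = 0.18). Photosystem genes (4 of 12 lower, 5 adjusted over the list alone, median −0.402, 0.125 with library totals), V-type ATPase genes (6 of 20 lower, 7 over the list alone, median −0.396, 0.14 with library totals), ammonium transporters and actin genes were also called lower at this step. With library totals the calls of photosystem genes (adjusted p = 0.116), V-type ATPase (adjusted p = 0.508) and actin genes (adjusted p = 0.116) were lost. With DESeq2 size factors those of ammonium transporters and actin genes were lost (both adjusted p = 0.0514), and none of the 4 held with an estimated correlation, photosystem genes giving adjusted p = 0.457. With library totals coats (adjusted p = 0.000691), urea cycle genes (adjusted p = 0.00599) and ammonium transporters (adjusted p = 0.0163) were called at the first step. Isoprenoid genes at the second step were called with the block (adjusted p = 0.0408) and not without it (adjusted p = 0.131, and 0.231 with library totals). The first count moved to 4126 and 4489 without HHQ 1 replicate 2 or 4 and to 4475 and 4161 without HHQ 10 replicate 1 or 2, and the second to 3156 without HHQ 10 replicate 4.

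At 72 h the change came mainly between 10 and 100 ng/ml. PYC1 was higher at 100 than at 10 ng/ml by 4.00 ± 0.30 on the log2 scale, mutS 11.9-fold and RFC3 9.53-fold higher, and Lhcf66 10.3-fold and Lhcf32 9.66-fold lower. Lhcf genes fell in 67 of 78 cases and rose in 0 (68 and 0 adjusted over the list alone; median −1.99, −0.981 with library totals, and adjusted p = 0.00884 with an estimated correlation). Photosystem genes fell in 10 of 12 (median −1, 0.0542 with library totals, and adjusted p = 0.183 with an estimated correlation), and replicative polymerases rose in 10 of 12 (median 2.25, and adjusted p = 0.0545 with an estimated correlation). V-type ATPase genes fell in 11 of 20 (median −0.646, 0.393 with library totals and adjusted p = 0.898 there, and adjusted p = 0.66 with an estimated correlation). Isoprenoid genes fell in 8 of 11 (median −1.23, −0.257 with library totals, and adjusted p = 0.184 with an estimated correlation). With library totals 5 isoprenoid genes fell and 3 rose. Ammonium transporters were not called (median −0.687, 0.253 with library totals; adjusted p = 0.156), but were with the block (adjusted p = 0.0323) or with library totals (adjusted p = 0.0107), which also called coats (adjusted p = 0.000569). The count was 10460, 5118 higher and 5342 lower (12865 and 1348 with library totals, 90.5% higher in place of 48.9%; median of all genes 1.01). From 1 to 10 ng/ml 173 genes changed, 128 higher and 45 lower (61 and 7 with library totals, 89.7% higher in place of 74%; median of all genes 0.134), with Arf4-2 3.63-fold and POLD1-1 3.49-fold higher. DNA recombination genes were called as a list at this step (0 of 14 changed, 2 higher adjusted over the list alone, median 0.264, and adjusted p = 0.0435 with an estimated correlation). This count was 434 with the replicate block within time, 562 with the axis as a covariate, 396 by DESeq2, 6 with the compared groups alone, 68 with replicates 1 and 2, 16 with replicates 3 and 4, 91 without HHQ 1 replicate 2 and 110 without HHQ 10 replicate 1.

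Whether the response differed between 24 and 72 h was tested as an interaction of dose and time. With 10 ng/ml the replication genes responded less at 72 h: POLE1 by −3.24 ± 0.60, POLD1-1 by −2.75 ± 0.37 and POLA1 by −2.73 ± 0.36 on the log2 scale. Lhcf39_2, lower at 24 h, differed by 1.13 ± 0.29. With 100 ng/ml the replication genes responded more at 72 h, POLA2 by 3.69 ± 0.52 and RFC5 by 3.68 ± 0.68, as did PYC1 (3.35 ± 0.40) and the aldolase gene FBA2 (6.33 ± 0.87). The syntaxin gene STXPM-2 (−2.08 ± 0.34), the calmodulin gene CAM1 (−1.58 ± 0.39) and AMT13 (−1.44 ± 0.28) had lower log2 fold changes at 72 h. For AMT13, called lower than vehicle at 72 h, this was a larger fall and not a weaker response.

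The interaction called 381 genes at 10 ng/ml, 54 with a larger and 327 with a smaller log2 fold change at 72 h (16 and 224 with library totals; median of all genes −0.126). That count was 690 by DESeq2, 224 with the compared groups alone, 805 with the replicate block within time and 1038 with the axis as a covariate. At 100 ng/ml it called 1597, 894 larger and 703 smaller (882 and 219 with library totals, 80.1% larger in place of 56%, and 69.3% with DESeq2 size factors; median of all genes 0.233), and by DESeq2 and with the axis as a covariate the counts were 2504 and 3893. At 1 ng/ml no gene passed in edgeR, with 786 at an unadjusted p under 0.05 and 5 by DESeq2, and 1143 passed with the axis as a covariate. The replicative polymerase list differed at both doses, with medians of −2.33 and 2.74 (adjusted p = 0.000717 and 0.00448 with an estimated correlation), and DNA recombination genes at 100 ng/ml with a median of 1.27 (camera adjusted p = 0.0101, and adjusted p = 0.0234 with an estimated correlation). Of 12 replicative polymerase genes 6 differed downward at 10 ng/ml and 8 upward at 100 ng/ml (9 and 9 adjusted over the list alone). Of 78 Lhcf genes 1 differed upward at 10 ng/ml, or 40 adjusted over the list alone (median 0.793; camera adjusted p = 1.94e-18, and adjusted p = 0.132 with an estimated correlation). STXPM-2 and AMT13 lost their calls with library totals, at −1.75 and −0.999, and CAM1 when only the compared groups were fitted, at −1.44. With 72 h replicates 3 and 4 AMT13 (−0.78) and CAM1 (−1.44) were not called, nor was CAM1 with replicates 1 and 2 (−1.57).

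The vehicle cultures themselves changed between 24 and 72 h, which sets the background for the time course. DUR3 was 10.7-fold higher at 72 h (log2 fold change 3.42 ± 0.77), GLN5 3.85-fold and MIP2 3.10-fold higher, while Arf5-2 and Arf5-1 were 4.87-fold and 3.47-fold lower and 16PFK1 2.82-fold lower. V-type ATPase genes fell in 7 of 20 cases and rose in 0 (9 adjusted over the list alone; median −0.42; adjusted p = 2.18e-05, and adjusted p = 0.814 with an estimated correlation). The Lhcf share of counts was 13.5% ± 0.619 at 24 h and 9.77% ± 0.99 at 72 h (exact two-sided permutation p = 0.0286; 0.0458 adjusted), while 2 Lhcf genes were higher and 2 lower (0 and 0 adjusted over the list alone; median −0.24, adjusted p = 0.00705, and adjusted p = 0.833 with an estimated correlation). In total 1884 genes changed, 1038 higher and 846 lower; with library totals 517 were higher and 1486 lower (25.8% higher in place of 55.1%, and 41.4% with DESeq2 size factors; median of all genes −0.355). The count was 1060 and 3061 without vehicle replicate 3 or 4 at 24 h and 1246 without replicate 1 at 72 h; it was 3860 with 24 h replicates 1 to 3. It was 460 with the compared groups alone, 2926 by DESeq2 and 6058 with the axis as a covariate.

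Between the parent cultures and the vehicle cultures at 24 h, DNA replication genes and PYC1 fell steeply, and Lhcf and photosystem genes rose. RFC2 was 125-fold lower (log2 fold change −6.96 ± 0.53), POLE1 55.9-fold lower, and of 12 replicative polymerase and clamp loader genes 11 fell and 0 rose (11 and 1 adjusted over the list alone; median −4.37, and adjusted p = 7.17e-05 with an estimated correlation). PYC1 went from 196.9 ± 9.12 to 2.11 ± 0.32 CPM, and IDH1 was 64.8-fold lower. Photosystem and pigment genes rose in 11 of 12 cases (median 1.58, and adjusted p = 0.0392 with an estimated correlation) and Lhcf genes in 54 of 78, 0 falling (60 adjusted over the list alone; median 0.914; adjusted p = 3.37e-18, and adjusted p = 0.0746 with an estimated correlation). Lhcf36 was 58.0-fold higher and ENO1, named for enolase, 51.4-fold; Lhcf37, with 3 counts over the parent group, had a ratio of 455 (95% counting interval 156 to 2210).

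Glycolysis genes rose in 9 and fell in 2 of 19 cases (10 and 2 adjusted over the list alone, and adjusted p = 0.0746 with an estimated correlation), V-type ATPase genes rose in 14 of 20 (15 over the list alone, and adjusted p = 0.32 with an estimated correlation), and fatty acid genes in 4 of 9 (median 0.528, and adjusted p = 0.0392 with an estimated correlation). DNA recombination genes fell in 5 and rose in 1 of 14 cases (median −0.749, and adjusted p = 0.0392 with an estimated correlation). In total 5015 genes changed, 2600 higher and 2415 lower; with library totals 1333 were higher and 2420 lower (35.5% higher in place of 51.8%; median of all genes −0.141), and none of these list medians changed sign.

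Overlap between doses and times was counted per direction. At 24 h 2339 genes changed the same way with 10 and 100 ng/ml (1498 higher, 841 lower) and 58 in opposite ways, where independent lists of these sizes would share 648.4. Both comparisons used the same vehicle libraries. For a simulated baseline the vehicle and both HHQ groups were all drawn from the vehicle means, without change. Its correlation of log2 fold changes across genes averaged 0.505 and its covariance 0.179, beside 0.619 and 0.763 observed. With the vehicle libraries divided between the doses, 1091 to 1394 genes were shared and the correlation was 0.332 to 0.48 over 6 divisions. At 72 h 193 genes were shared (130 higher, 63 lower) and 18 opposite, against 57.5 for independent lists; the correlation of 0.439 lay below the simulated 0.503, the covariance was 0.435 beside 0.188, and divided vehicle libraries gave 36 to 161 shared genes with correlations of 0.00424 to 0.262. The simulated libraries varied independently. Same-numbered HHQ 10 and HHQ 100 libraries varied together (correlations of 0.12 to 0.422 at 24 h and 0.134 to 0.45 at 72 h), which the simulation does not allow for. Genes are not independent replicates, and no p-value is attached to these correlations.

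Across times 7477 genes changed the same way with 100 ng/ml at 24 and 72 h (3768 higher, 3709 lower) and 184 in opposite ways, against 2512.4 for independent lists, with a correlation across genes of 0.683. Lhcf32, Lhcf21_1, PKS5 and Arf4-1 were among the genes called the same way at both times. With 10 ng/ml 207 genes were shared and 1 was opposite, against 16.3 for independent lists (correlation 0.31).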

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

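Tests of a few abundant genes, of uniform background reads at HHQ 100, of scaling and of the axis as a covariate were chosen after the results were seen. The test of an offset along the axis was added after these, before its own value was seen; the other tests below were planned before their results.

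In 16 of 108 sets of 4 libraries (12 measures in 9 groups) the highest or lowest library lay far from the other 3, where chance gives about 1 in 20, or 5.4. Scaling factors stood apart in vehicle replicate 4 at 24 h (0.67 against 1.04 to 1.10) and HHQ 10 replicate 4 at 24 h (0.927 against 1.22 to 1.27). The 10 most abundant genes took 10.2% of counts in parent replicate 1 against 11.6% to 11.9%. On the axis of deviation from group means, parent replicate 1 lay at 63.2 (others −24.9 to −14.2), vehicle replicate 4 at 82.3 (−35.5 to −20) and HHQ 10 replicate 4 at 77.1 (−29.5 to −22.9), both at 24 h. Single-gene levels in CPM stood apart for Lhcf32 in HHQ 100 replicate 4 at 72 h (4428 against 2584 to 2620) and PKS5 in vehicle replicate 3 at 24 h (1.25 against 3.64 to 3.74). Arf4-1 did so in vehicle replicate 4 at 24 h (37.9 against 17.7 to 19.6), vehicle replicate 2 at 72 h (46.1 against 30.7 to 32) and HHQ 10 replicate 2 at 72 h (131 against 98 to 101.1). POLD1-1 did so in parent replicate 1 (18.5 against 9.97 to 11.1) and vehicle replicate 4 at 24 h (1.29 against 1 to 1.05), POLA1 in HHQ 10 replicate 4 at 72 h (3.73 against 4.61 to 4.77), and PYC1 in vehicle replicate 4 (2.58 against 1.89 to 2) and HHQ 100 replicate 3 at 24 h (15.96 against 6.42 to 7.57).

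The response differed between 72 and 24 h for 381 genes at 10 ng/ml and 1597 at 100 ng/ml. At 10 ng/ml the differences in log2 fold change, tested as interactions, were −3.24 (POLE1), −2.91 (POLD1-2), −2.75 (POLD1-1), −2.73 (POLA1) and 1.13 (Lhcf39_2), with a median of −2.33 for the replicative polymerases. At 100 ng/ml they were 6.33 (FBA2), 4.34 (MAN1), 3.69 (POLA2), 3.68 (RFC5), 3.35 (PYC1), −2.08 (STXPM-2), −1.58 (CAM1), −1.52 (Lhcf44) and −1.44 (AMT13), with medians of 2.74 for the replicative polymerases and 1.27 for DNA recombination genes. Lhcf39_2 and Lhcf44 lost their calls without single libraries.

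Libraries of a group differed along an axis holding 25.9% of the variance of deviations from group means (the next held 7.84%). Read depth as its source is argued against, since the axis correlated at 0.999 with itself after every library was thinned to the smallest total. Uniform background reads are argued against too: of 10 classes of genes by abundance, the lowest moved 0.946 times as much as the fifth. Gene loadings found at 24 h with the parent cultures and at 72 h correlated at 0.684 across genes, which fits 1 property of the libraries at every time, but regrouped libraries reached 0.673. Whether the property arose in culture or in library preparation was not tested, and no biological explanation was tested.

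With 100 ng/ml HHQ low and middle abundance genes rose against the most abundant ones: at 24 h the 100 most abundant genes took 17.6% of counts in place of 29.6% in vehicle. A few abundant genes losing counts is argued against as the whole cause, since without them in the totals the median log2 ratio of mean CPM by library totals, with 0.1 CPM added, was still 0.577 (0.835 with them). Uniform background reads are argued against, because the gain in CPM was 11.2 times larger in the eighth of 10 abundance classes of genes than in the second. The axis along which libraries of a group differed has a similar shape. Over 2 SD of it the median log2 change was −0.262 in the lowest abundance class and 0.594 in the highest. HHQ 100 at 72 h was offset from vehicle by −1.75 SD along it, the direction in which low abundance genes rise. No offset was estimated for this dose at 24 h. An effect of HHQ on the spread of transcript levels, or on total RNA per cell, may account for the pattern. It was not tested and not separated from a shift along that axis.

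Replication genes rose with 10 ng/ml at 24 h and with 100 ng/ml at 72 h. With library totals the median of the 12 genes for HHQ 10 at 24 h was 3.99 in place of 3.73. Another scaling shifts all genes by about the same amount, here their median from −0.00946 to 0.262. This check, written after the results, could thus not have removed the rise. The values show only that the choice between these scalings does not account for it. The axis as a covariate (median 3.73) decides nothing, since its scores average 0 in each group, but an offset between groups along it is argued against as the whole cause at 24 h: with the offset, estimated from genes outside the DNA lists, taken out, the median log2 difference was 3.12 (quartiles 2.16 and 3.97, 3.07 before). A state shared with the parent cultures, where these genes were also high, stays open: across genes outside the DNA lists, the differences correlated with parent against vehicle at 0.118 for 10 against 1 ng/ml at 24 h (8 of 35 splits as large, furthest −0.187) and at 0.298 for 100 ng/ml at 72 h (3 of 35, furthest 0.31). A change in the share of cells replicating DNA is a hypothesis that these libraries alone cannot test.

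Other splits of the same libraries into 4 and 4, fitted alone, were counted for each comparison. Only the real split, 1 of 35, gave as many genes for HHQ 10 at 24 h (2368, highest other 2), HHQ 100 at 24 h (10953, highest other 2) and 72 h (9886, highest other 2), HHQ 100 against 10 at 24 h (7295, highest other 1) and 72 h (7928, highest other 2), vehicle over time (460, highest other 13) and vehicle against parent (4165, highest other 0). Among splits that ignore replicate numbers, chance alone is argued against there, at a share of 1 in 35 that was not adjusted over the comparisons. Where the numbers pair the libraries (HHQ 10 at 24 h, HHQ 100 against 10 at both times), 7 other splits part all 4 pairs, too few for a share under 0.05, and the highest of them gave 0. For HHQ 1 the real count was 0 at both times, which every split reaches (35 of 35, highest others 9209 at 24 h and 6560 at 72 h), so the splits say nothing there. Chance could not be excluded for HHQ 10 at 72 h (57; 2 of 35, highest other 5354), HHQ 10 against 1 at 24 h (6082; 2 of 35, highest other 6771) and at 72 h (6; 3 of 35, highest other 5752). At 72 h these larger splits set replicates 1 and 2 against 3 and 4, a structure of the libraries; among splits that part all 4 pairs the highest other was 0 for both, and the blocked counts were 725 and 434. At 24 h the splits with 9209 and 6771 genes joined HHQ 1 replicate 1 to replicates 1 to 3 of the other group, again a structure of the libraries. Of 100 groupings counted for each interaction, the real one included, 3 reached 224 at 10 ng/ml (highest other 473). Only the real one reached 1470 at 100 ng/ml (highest other 282). The other groupings exchanged HHQ and vehicle libraries within 1 or both times and so removed the HHQ response there. They cannot tell a response that differs between times from an equal response at both, so chance was not excluded for either interaction. Regroupings that respect the pairs of HHQ 10 and vehicle libraries were not counted apart. At 1 ng/ml the real count was 0, which all 100 reach (highest other 5082), so nothing follows from them.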

How the results depend on the processing

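Tests with library totals as scaling, the replicate block within time, the deviation axis as a covariate and subsets of libraries were chosen after the results were seen; the others were planned. Counts stayed within 1.5 times in every setting for HHQ 100 against vehicle at both times, HHQ 100 against HHQ 10 at 72 h and vehicle 24 h against parent. For counts that moved, the cause was not tested. A fold minimum, fewer libraries, another tool or an axis computed from the same genes changes what is called by construction.

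With an absolute log2 fold change of at least 1, counts were 1759 (HHQ 10, 24 h), 4116 (HHQ 10 against 1, 24 h), 2943 (HHQ 100 against 10, 24 h), 1081 (vehicle 72 h against 24 h) and 4886 for the 7477 genes shared between times. The DESeq2 Wald test gave 12 and 8 (HHQ 1, 24 and 72 h), 578 (HHQ 10, 72 h), 396 (HHQ 10 against 1, 72 h), 5, 690 and 2504 (interactions at 1, 10 and 100 ng/ml) and 2926 (vehicle over time). The compared groups alone gave 57, 6, 224 and 460 for HHQ 10 at 72 h, HHQ 10 against 1 at 72 h, the 10 ng/ml interaction and vehicle over time. Library totals gave 135, 68 and 240 for the first 3 of these.

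The planned replicate block moved no count by over 1.5 times. Within time, the block gave 1237 (HHQ 1, 24 h), 5479 and 725 (HHQ 10, 24 and 72 h), 10503 and 434 (HHQ 10 against 1), 9273 (HHQ 100 against 10, 24 h), 805 and 3243 (interactions at 10 and 100 ng/ml) and 6981 (vehicle over time); where the numbers pair the libraries, it changed no other list call than the 2 lost for DNA recombination genes (adjusted p = 0.0513 and 0.18, at medians of 0.766 and −0.62 in place of 0.714 and −0.623) and the 2 gained for isoprenoid genes and ammonium transporters (0.0408 and 0.0323). Same-numbered libraries did not all vary together for HHQ 1 (−0.168 to 0.362) and HHQ 100 (0.0137 to 0.448) at 24 h, HHQ 100 at 72 h (0.0248 to 0.318), HHQ 10 against 1 at 24 h (−0.0668 to 0.306), vehicle over time (−0.299 to 0.138) and vehicle against parent (−0.159 to 0.105). With the axis as a covariate counts were 3466 (HHQ 1, 24 h), 6191 and 875 (HHQ 10), 10939 and 562 (HHQ 10 against 1), 9740 (HHQ 100 against 10, 24 h), 1143, 1038 and 3893 (interactions) and 6058 (vehicle over time).

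With 24 h replicates 1 to 3, HHQ 1 at 24 h gave 1 gene and vehicle over time 3860. With 72 h replicates 1 and 2, counts were 75 (HHQ 10), 68 (HHQ 10 against 1), 149 (10 ng/ml interaction) and 3850 (vehicle over time), and with 72 h replicates 3 and 4 they were 17, 16 and 242 for the first 3, 3 for HHQ 1 and 4 for its interaction. Lists called were 2 at 24 h and 4 at 72 h for HHQ 100; an estimated correlation gave 1 and 2, fry, which does not compare a list with other genes, 15 and 16, and library totals 4 at 24 h.

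Leaving out each library in turn gave 0 to 2 (HHQ 1, 24 h; 1 without vehicle replicate 3 or 4, 2 without HHQ 1 replicate 3), 2230 to 3033 (HHQ 10, 24 h), 8786 to 10454 (HHQ 100, 24 h), 0 to 1 (HHQ 1, 72 h; 1 without HHQ 1 replicate 3), 161 to 210 (HHQ 10, 72 h; 165 without vehicle replicate 1, 161 without HHQ 10 replicate 4) and 10338 to 12381 (HHQ 100, 72 h). Dose steps gave 4126 to 8423 (4126 and 4489 without HHQ 1 replicate 2 or 4, 4475 and 4161 without HHQ 10 replicate 1 or 2) and 3156 to 4955 at 24 h (3156 without HHQ 10 replicate 4), and 91 to 155 (91 without HHQ 1 replicate 2, 110 without HHQ 10 replicate 1) and 7882 to 10722 at 72 h. Interactions gave 0 to 0, 270 to 429 and 1248 to 1658. Vehicle over time gave 1060 to 3061 (1060 and 3061 without 24 h replicate 3 or 4, 1246 without 72 h replicate 1), and vehicle against parent 4277 to 4931. Lists called were 2 to 3 (3 without vehicle replicate 2 or HHQ 100 replicate 2) and 4 to 6 (6 without vehicle replicate 2).

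For 343 results on 207 named genes, 5936 of 6235 values kept direction and call, 256 lost the call, 28 gained one and 15 changed sign, all with library totals. At HHQ 100, 24 h, these log2 fold changes became 0.11 (AMT17), 0.048 (NAR4), 0.14 (GGT2), 0.17 (ATPVE), 0.27 (ATPVG), 0.33 (ATPVc/c), 0.31 (ATPVG2) and 0.026 (ECH12), and at 72 h 0.069 (CPO), 0.0096 (GGT2), 0.59 (MSRA2), 0.28 (ATPVE), 0.24 (ATPVG2), 0.47 (ATPVF) and 0.17 (ARPC1). In data simulated with the depth and spread of these libraries, and few changed genes, most 2-fold changes were not recovered. With few changed genes the adjusted threshold is stricter than at HHQ 100, where 10886 and 12243 genes were called. The simulation therefore does not give the sensitivity of those comparisons.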

Other observations

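The test of parent state below was written before its result was seen; the gene levels were chosen after their values were seen.

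PYC1, IDH1 and 16PFK1 were high in the parent cultures, lower in vehicle and higher again with 100 ng/ml HHQ at 72 h. PYC1 stood at 196.9 ± 9.12 CPM in the parent cultures, 2.11 ± 0.319 in vehicle at 24 h and 10.7 ± 2.85 and 9.33 ± 4.45 with 10 and 100 ng/ml HHQ at 24 h (SD, 4 libraries each). At 72 h it stood at 1.06 ± 0.121 in vehicle, 3.02 ± 0.368 with 10 ng/ml and 48.4 ± 11.8 with 100 ng/ml. IDH1 went from 529.9 ± 32.2 CPM in the parent cultures to 3 ± 1.08 in vehicle at 72 h and stood at 55.4 ± 20.2 with 100 ng/ml, and 16PFK1 stood at 540.7 ± 56.8, 22.8 ± 3.83 and 158.4 ± 12.5 CPM in these groups. ENO1 did not follow this order: it stood at 10.5 ± 3.91 CPM in the parent cultures, 400.8 ± 121 in vehicle at 72 h and 415.5 ± 41.7 with 100 ng/ml.

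Across all genes outside the DNA lists a general return towards the parent profile was not established. The correlation of 0.298 for 100 ng/ml at 72 h was reached in size by 3 of 35 splits, the real one included.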
